A study of Mus musculus with 3 samples.

How the data were processed

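Total RNA was measured in 3 libraries from CD43-negative splenic B cells of C57BL/6 mice, 1 library each for DMSO, JQ1+ at 80 nM and flavopiridol at 30 nM, after 3 days with lipopolysaccharide and interleukin-4. Per the labels' protocols, RNA was extracted with Trizol, ribosomal RNA was depleted with Ribo-Zero, and libraries were made by standard Illumina protocols. Depletion without selection for poly(A) keeps histone, unspliced and other non-polyadenylated RNA, which therefore appears in the values. Groups were taken from the treatment label of each sample, and the culture label of the JQ1+ and flavopiridol samples repeats the DMSO wording. Whether the cultures came from the same mice is not stated.

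Each library has a table of 33700 genes with an Ensembl identifier, a symbol, a gene type, a count and an RPKM. The counts are whole numbers of reads per gene that were not normalised, per the file headers. The RPKM values were scaled by the authors to the length of the gene and to a library total, per the file headers. The submitters' processing notes name the genome build mm9. The aligner, the counting program, the annotation, the treatment of reads with several matches and the use of strand are not given in the sources used here. The tables hold no coordinates, and because the annotation at hand (GENCODE M21) is of a later build, no positions are given; it was used for gene lengths and GC content by identifier alone.

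The total behind the RPKM was computed from count, RPKM and GENCODE M21 exon length over genes with a matching length. Between 46.3% and 46.9% of well-counted genes matched within 0.1%. The totals were 21047852 for DMSO, 18846553 for JQ1+ and 17162740 for flavopiridol, against count sums of 59786847, 51247080 and 50184508, so the counts summed to 2.84, 2.72 and 2.92 times the RPKM total. Even counts were in excess: in DMSO 1267 genes had a count of 1, 1716 a count of 2, 521 a count of 3 and 769 a count of 4. The counts are therefore not independent fragments. For intervals, counts were divided by 2.83 in each library, and the exact conditional binomial 95% interval of the ratio was put on the RPKM scale. Intervals and floors cover counting error only, not differences between cultures. A gene with no reads could still be present at up to 3 counts, which is 0.0502 CPM in DMSO, 0.0585 in JQ1+ and 0.0598 in flavopiridol. These floors use undivided counts, so they are too low where counts are not independent fragments.

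Library make-up was compared from the counts. Protein-coding genes took 82.0%, 80.4% and 84.0% of counts in DMSO, JQ1+ and flavopiridol, the 10 most counted genes 11.3%, 13.6% and 9.99%, and mitochondrial genes 3.90%, 4.48% and 4.74%.

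With 1 library per group no count model could estimate spread, so none was used. The change of a gene was log2((a + 1)/(b + 1)) of RPKM, with a pseudocount of 1, which understates changes of low genes. For the 94 symbols with several rows the row with the highest mean was used, giving 33605 symbols, of which 14790 had a 3-library mean of at least 1 RPKM. A log2 change of at least 1 in size was called. Named genes were the 12 largest rises and 12 largest falls for each drug and the 6 on each side between the drugs, among genes with a mean of at least 5 RPKM, without small RNAs, histones and gene models lacking a name. Up to 4 members per described list with the largest change, a fixed set of B cell and drug target genes and the antibody constant regions were added. Some genes within this rule are not reported here. Genes described outside it are said to have been chosen after their values were seen.

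The gene lists were 29, fixed before the data were examined, as were the size rule, the named genes and most alternatives. For each list the median change of measured members was placed among 10000 random lists of the same size matched on mean expression in 20 bins. Of these, 24 lists had at least 6 measured members and were called, which gave 72 list comparisons; 39 stood apart, where 3.6 would by chance if genes were independent. Lists share 19 genes. The lists were class switch recombination and hypermutation, MYC targets, plasma cell, endoplasmic reticulum folding, naive B cell, B cell identity, germinal centre, interleukin-4 response, NF-kB and inflammation, DNA replication, G2/M, histones, p53 targets, BCL2 family, pause-release factors, immediate early, interferon-stimulated, glycolysis, oxidative phosphorylation, cholesterol synthesis, ribosomal proteins, integrated stress, surface receptors, and markers of T cells, myeloid cells, dendritic cells, cytotoxic cells, erythroid cells and stroma. Supt5h, Ighd, Hmgcs1, Bcl2a1a and Bcl2a1d were not matched by symbol.

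Some choices were made after the data were seen: the minimum of 6 members, the division of counts for intervals, the simulation of counting noise, scaling by the sum of counts, the restriction to protein-coding genes, the rule that adds the counting interval, and the rules that judge whether a correlation or a named gene moved. Counting noise was simulated 100 times by drawing all 3 libraries from the DMSO level of 14742 genes at the RPKM totals, and the same draws gave the correlation and overlap expected from the shared DMSO library. The procedure was tested on simulated data for JQ1+ against DMSO over 14790 genes with 200 changed. It recovered 100% of 4-fold changes, called 1% of 1.5-fold changes and called 0.333% of 11123 unchanged genes with at least 5 RPKM. Alternatives changed the pseudocount, the scaling, the row of a repeated symbol, the expression minimum, the fold rule and the gene types. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.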

Results

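RNA was measured in mouse splenic B cells that lacked surface CD43, the marker used to take out activated B cells and most non-B cells. The C57BL/6 cells were cultured for 3 days with lipopolysaccharide, a bacterial product sensed by Toll-like receptors, and interleukin-4, a T cell cytokine. This mixture drives proliferation and switching of the antibody class towards IgG and IgE. The cultures also received DMSO as vehicle, JQ1+ at 80 nM, or flavopiridol at 30 nM. JQ1 displaces BET proteins from acetylated chromatin. Flavopiridol inhibits cyclin-dependent kinases including Cdk9, the kinase that releases paused RNA polymerase. The comparisons therefore ask which transcripts differed after each drug in activated B cells, and how far the same genes differed with both. RPKM is scaled to each library's own total, so a change shared by all transcripts would not show. After 3 days, direct effects of a drug cannot be told apart from indirect ones. The compounds are not structurally related and were used at different doses.

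There were 3 libraries, 1 per treatment, so no difference reported here has a replicate check and no p-value is given. The deposited counts summed to 59786847 in the DMSO library, 51247080 in the JQ1+ library and 50184508 in the flavopiridol library. Among 14790 genes with a mean of at least 1 RPKM, a gene is said to have risen or fallen when log2((RPKM + 1)/(RPKM + 1)) was at least 1 in size, a 2-fold change. Ratios in plain RPKM carry 95% intervals that cover counting error only. A gene list is said to stand apart when its median change lay outside the central 95% of 10000 random lists of like expression, which describes these libraries and is not a test of the drugs.

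The first comparison set JQ1+ against DMSO. Transcripts of the IgG and IgE constant regions were lower in JQ1+, by amounts that differed among them. The IgE constant region gene Ighe fell from 470.0 to 5.76 RPKM, 81.6-fold lower (interval 62.4 to 109.9). Of 29 measured interferon-stimulated genes 27 fell, and the list median was -2.50. Myc, the growth-promoting transcription factor, fell from 194 to 76.2 RPKM, 2.55-fold lower (interval 2.39 to 2.71).

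In all, 293 genes rose and 782 fell with JQ1+. Unchanged libraries drawn with counting noise alone gave on average 135 higher and 148 lower. Among genes with a mean of at least 5 RPKM, 138 rose and 471 fell, against 29.6 and 33.8 from counting noise. The median of all genes was -0.08.

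The other switched isotypes fell less than Ighe. Ighg1, the main isotype induced by interleukin-4, fell from 3257 to 1479 RPKM, 2.20-fold lower (interval 2.15 to 2.25). Ighg3 fell from 123 to 44.9 RPKM, Ighg2b from 42.9 to 14.8 and Ighg2c from 6.84 to 2.15. The IgM gene Ighm stood at 35234 RPKM in DMSO and 61288 in JQ1+, a log2 change of 0.80, and the kappa light chain gene Igkc had a log2 change of 0.57. As a percentage of the Ighm RPKM, Ighg1 was 9.24 in DMSO and 2.41 in JQ1+, and Ighe was 1.33 and 0.0094. Unswitched cells also transcribe these constant regions, so these ratios are not fractions of switched cells. The class switch and hypermutation list did not stand apart: its median was -0.11 at percentile 32.8, and of 31 members only Hmces, a sensor of abasic DNA, rose.

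**Figure D1:**
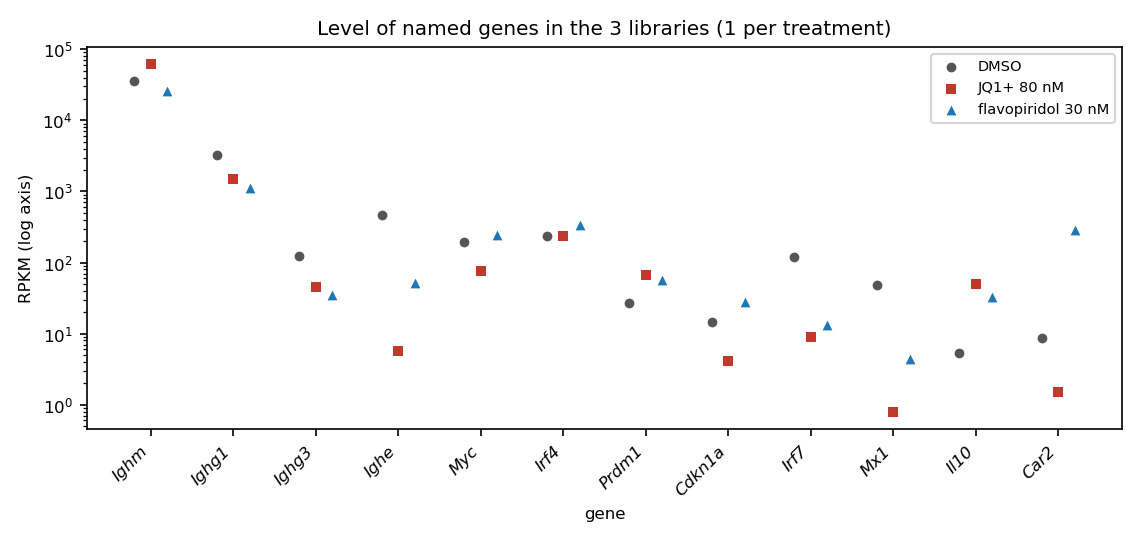
RPKM of 12 named genes in the DMSO, JQ1+ and flavopiridol libraries, 1 point per library, on a log axis and without error bars because each treatment had 1 library. Ighe lay at 470.0 RPKM in DMSO, 5.76 in JQ1+ and 52.2 in flavopiridol, and Car2 at 8.68, 1.498 and 289.

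Antiviral genes led the falls with JQ1+. Oas3, which makes the activator of RNase L, fell from 72.4 to 0.761 RPKM, 95.1-fold lower (interval 64.1 to 142). Usp18, which removes Isg15 from proteins, the dynamin-like GTPase Mx1 and the receptor-transporting protein Rtp4 fell by log2 changes of -4.98, -4.77 and -4.44. The interferon list lay below all 10000 random lists. Other genes among the largest falls were Lgals3bp, a secreted galectin-binding protein (-5.69), the protease inhibitor Slpi (-5.66), Ido1, which degrades tryptophan (-5.30), Ifitm3, which restricts virus entry (-5.08), the cytochrome oxidase subunit Cox6a2 (-5.04) and Il1r2, the decoy receptor for interleukin-1 (-4.77). Of 6 dendritic cell markers measured, 3 fell: Batf3 from 55.9 to 2.98 RPKM, Flt3 from 26.6 to 2.55 and Bst2 from 247 to 43.0. Bst2 is also a member of the interferon list. The plasmacytoid marker Siglech was at 0 RPKM in DMSO, where 3 undivided counts would be 0.0502 CPM.

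The genes that rose most with JQ1+ included secreted immune mediators. The chemokine gene Ccl3 rose from 8.62 to 96.0 RPKM, 11.1-fold (interval 8.33 to 15.3), and Ccl4 from 2.02 to 16.8. Il10, which encodes an anti-inflammatory cytokine, rose from 5.26 to 49.8 RPKM, 9.47-fold (interval 7.12 to 13.0). Lipoprotein lipase, Lpl, rose from 0.399 to 9.90 RPKM, and Pdcd1, the gene of the inhibitory receptor PD-1, from 2.93 to 25.1. Also on this list were Rpl27-ps2 (3.91), a pseudogene whose reads cannot be told apart here from those of its parent and copies, the kappa variable gene Igkv8-21 (2.03), the epoxide hydrolase Ephx1 (1.97), the phosphatase Ptprj (1.97), S1pr1, which guides lymphocyte exit from tissue (1.96), Zc3h12c, of a family of RNA-degrading proteins (1.94), and the glycosyltransferase Gcnt1 (1.92). Prdm1, which drives plasma cell differentiation, rose from 26.9 to 67.2 RPKM.

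Metabolic and stress lists stood lower with JQ1+. The glycolysis list had a median of -0.90, with 9 of 19 members lower and the rest within 2-fold. The lactate exporter Slc16a3 fell from 11.0 to 0.778 RPKM, and the enzymes Aldoc (-2.51), Tpi1 (-1.54) and Eno1 (-1.36) fell. Integrated stress response genes had a median of -0.65, with 6 of 25 lower, led by asparagine synthetase, Asns (-1.79), Trib3 (-1.66), Cebpb (-1.59) and Atf3 (-1.45). MYC targets had a median of -0.33 at percentile 0.010, although only Ldha of 35 fell (-1.21), and p53 targets had a median of -0.35 at percentile 0.070. Within the p53 list the cell cycle inhibitor Cdkn1a (-1.60), Sesn2 (-1.36) and Phlda3 (-1.14) fell, and Trp53inp1 rose (1.17). Cholesterol synthesis had a median of -0.33 and cytosolic ribosomal proteins -0.19, both below the random range. After subtracting the median of genes of like GC content and length they were -0.23 and -0.066. Such a subtraction also takes out the shift shared by all genes, here a median of -0.08. In these lists no cholesterol gene of 22 and only Rps19 of 57 ribosomal protein genes passed the 2-fold rule.

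Lymphocyte programmes moved in both directions with JQ1+. Germinal centre genes stood lower, with a median of -0.41 over 13 members, and the DNA glycosylase Neil1 fell (-2.92). The NF-kB and inflammatory list stood lower, with a median of -0.22, 7 of 32 members lower and 3 higher, a call that was lost with a minimum of 5 RPKM; the median was -0.087 after subtracting that of genes of like GC content and length. The cytokine genes Il6 (-3.78) and Ebi3 (-2.94) fell while Ccl3, Il10 and Ccl4 rose. Endoplasmic reticulum folding genes stood higher with a median of 0.18, although none of 31 passed 2-fold. B cell identity genes stood higher at 0.15, with Ms4a1, the CD20 gene (1.29), the kinase Syk (1.26) and Cd180 (1.15) among 4 that rose, and Vpreb3 (-2.28) the one that fell. Plasma cell genes stood higher at 0.12, with Prdm1 and Creb3l2 (1.25) higher and Cd28 (-1.14) lower. Immediate early genes had a median of 0.07, above the random range, but a mean of -0.14; 5 of 30 fell, among them Ier3 (-1.64), Fosl2 (-1.60) and Myc, and none rose.

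With JQ1+ the remaining lists lay inside the random range or just outside it. Histone genes had a median of 0.03 at percentile 98.9 and oxidative phosphorylation genes 0.03 at 98.0, both called higher at that small size, the latter in 5 of 9 alternatives. The G2/M (0.04, percentile 97.485), pause-release factor (0.06, percentile 97.43) and BCL2 family (-0.28, percentile 2.74) lists lay just inside that range, and the DNA replication (-0.10), naive B cell (0.06), interleukin-4 response (-0.15) and surface receptor (-0.20) lists did not stand apart either. Among single members of these lists that still passed 2-fold, the chromatin organiser Satb1 (-2.70), the CD30 gene Tnfrsf8 (-2.68) and the adhesion receptor Cd44 (-1.49) fell, and S1pr1 (1.96) and the elongation factor Ell3 (1.04) rose. Cdk9 stood at 35.2 RPKM in DMSO and 32.1 in JQ1+, and Hexim1, an inhibitor of Cdk9, at 48.4 and 63.0. Irf4 (0.00), Pax5 (0.29), Mcl1 (0.46), Il4ra (-0.15), Ccnd2 (-0.57), Bcl6 (-0.90) and Bcl2 (-0.92) were within 2-fold by the rule with the pseudocount. In plain RPKM Bcl6 was 2.04-fold lower with JQ1+ (interval 1.74 to 2.40).

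The second comparison set flavopiridol against DMSO. Ighe fell again, from 470.0 to 52.2 RPKM, 9.0-fold lower (interval 8.15 to 9.96). Interferon-stimulated genes fell in 25 of 29 cases with a list median of -2.04. Unlike with JQ1+, Myc did not fall and stood at 243 RPKM, 1.25 times its DMSO level (interval 1.196 to 1.31). Among the named genes the largest log2 change upwards, with the pseudocount, was that of Car2 (4.90), a carbonic anhydrase, which rose from 8.68 to 289 RPKM, 33.3-fold (interval 27.6 to 40.3).

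With flavopiridol 525 genes rose and 426 fell, where counting noise alone gave 138 and 160. Among genes of at least 5 RPKM, 229 rose and 256 fell, against 31.0 and 36.1. The median of all genes was 0.13, and the balance depended on it: 44.8% of called genes were lower as deposited and 58.2% after each library was rescaled by the median of ratios, which moved the median of all genes by -0.13.

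Ighg1 fell to 1116 RPKM with flavopiridol, 2.92-fold lower (interval 2.84 to 3.00), Ighg3 to 35.3 and Ighg2b to 15.6. Ighg2c was 5.04 RPKM, within 2-fold of DMSO. Ighm stood at 25661 RPKM (-0.46) and Igkc at 25754 (-0.72). As a percentage of the Ighm RPKM, Ighg1 was 4.35 and Ighe 0.204. The class switch list did not stand apart (median 0.16, percentile 67.3).

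The interferon genes that fell most with flavopiridol were Oas3 (-4.19), Usp18 (-3.41), Rtp4 (-3.37), Mx1 (-3.19), Oas2 (-3.12) and Irf7, a master regulator of interferon responses (-3.10). Alongside them Slpi (-3.86), Il1r2 (-3.66), the interferon-inducible Pydc4 (-3.52) and Lgals3bp (-3.34) fell. Oas genes have close paralogues, so the split of reads among them is uncertain. Of the 6 dendritic cell markers, Batf3 fell from 55.9 to 11.1 RPKM and Bst2 from 247 to 99.8. Among myeloid markers Emr1, the F4/80 gene, rose from 0.922 to 9.47 RPKM and Fcgr4 fell from 2.91 to 0.835.

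Rises with flavopiridol included Atp1b1, a sodium pump subunit (4.03), Lpl (3.71), Rpl27-ps2 (3.79), the metallothioneins Mt2 (3.32) and Mt1 (2.68), the G protein regulators Rgs2 (3.04) and Rgs16 (2.46), the CD30 ligand gene Tnfsf8 (2.61) and Rai14 (2.42). Ccl3 rose from 8.62 to 53.2 RPKM, Il10 from 5.26 to 32.4 and Prdm1 from 26.9 to 56.5.

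The p53 targets stood higher with flavopiridol, with a median of 0.55 above all random lists. Of 23 members 4 rose, Plk2 (1.54), Phlda3 (1.39), Zmat3 (1.20) and Perp (1.18), and none fell; Cdkn1a had a log2 change of 0.89. MYC targets stood higher with a median of 0.45, and the mitochondrial chaperone Hspd1 (1.10) and the nucleotide hydrolase Dctpp1 (1.10) rose. Oxidative phosphorylation genes (0.34) and endoplasmic reticulum folding genes (0.31) stood higher with no member past 2-fold. After subtracting the median of genes of like GC content and length they were 0.163 and 0.151. The subtraction also takes out the shift shared by all genes, here a median of 0.13.

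Glycolysis genes stood lower with flavopiridol, with a median of -0.45 and 3 of 19 members lower: Slc16a3 (-2.20), Aldoc (-2.08) and Aldoa (-1.01). Integrated stress genes had a median of -0.33, and Chac1 (-1.64), Trib3 (-1.18), Atf3 (-1.02) and Asns (-1.004) fell. Germinal centre genes had a median of -0.61, with Neil1 (-2.36) and Mef2b (-2.03) among 4 of 13 that fell and Mybl1 (1.35) higher. The interleukin-4 list (-0.14) stood below random lists at percentile 2.40, a call lost with a pseudocount of 0.1, while its members went both ways, the chemokine gene Ccl22 higher (1.93) and the signalling inhibitor Socs3 lower (-1.30). Histones (-0.11), cholesterol synthesis (-0.10), B cell identity (-0.05) and ribosomal proteins (-0.05) lay slightly below random lists, with Fcrla (1.07) and Rps23 (1.25) the members past 2-fold. Over members, the intervals of the interleukin-4 (-0.73 to 0.52) and B cell identity (-0.47 to 0.30) medians included the random medians of 0.09 and 0.12.

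The DNA replication (0.19), G2/M (0.18), plasma cell (0.26), BCL2 family (0.24), pause-release factor (0.11), NF-kB (0.06), surface receptor (0.04), naive B cell (0.03) and immediate early (-0.02) lists did not stand apart with flavopiridol. Members of these that rose included the plasma cell surface gene Sdc1 (1.23), Eaf2 (1.26), the pro-apoptotic Bcl2l11 (1.31), Cd24a (1.49) and Rgs1 (1.91), and Ltb fell (-2.09). Cdk9 stood at 29.3 RPKM and Hexim1 at 40.9. Irf4 (0.52), Pax5 (0.26), Mcl1 (0.26), Ccnd2 (0.23), Bcl2 (0.19), Il4ra (-0.30) and Bcl6 (-0.95) were within 2-fold by the rule with the pseudocount. In plain RPKM Bcl6 was 2.13-fold lower with flavopiridol (interval 1.81 to 2.53).

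The third comparison set the drugs side by side. Ighe was 9.07-fold lower in JQ1+ than in flavopiridol (interval 6.81 to 12.4). Myc was 3.19-fold lower in JQ1+ (interval 3.00 to 3.39) and Cdkn1a 6.71-fold lower (interval 5.11 to 8.91). Ighm and Igkc went the other way, with Ighm 2.39 times as high in JQ1+ (interval 2.38 to 2.40) and Igkc 2.45 times (interval 2.43 to 2.48). The largest difference was in Car2, 193-fold lower in JQ1+ (interval 121 to 324).

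Between the drugs 304 genes were at least 2-fold higher in JQ1+ and 1016 lower, where counting noise alone gave 164 and 150. The median of all genes was -0.21, and rescaling by the median of ratios moved the lower share of called genes from 76.97% to 57.3%. The other genes furthest below flavopiridol were the glycosyltransferase B3gnt7 (-4.32), the serotonin receptor Htr7 (-3.73), the homeobox factor Hlx (-3.40), the signalling adaptor Dok2 (-3.16) and Tnfsf8 (-3.12). Hlx, Htr7 and Dok2 were within 2-fold of DMSO under flavopiridol, at 0.13, -0.31 and -0.32. Those furthest above were variable region genes, Igkv4-74 (2.71), Igkv4-71 (2.62), Igkv4-86 (2.498), Igkv4-57-1 (2.34), Ighv7-4 (2.29) and Igkv4-61 (2.26), whose similar sequences make the split of reads uncertain.

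By list, p53 targets (-0.91, 9 of 23 lower), MYC targets (-0.85, 5 of 35 lower), the interferon list (-0.68, 11 of 29 lower), BCL2 family genes (-0.59, 4 of 14 lower) and glycolysis (-0.48, 0 of 19 past 2-fold) were lower in JQ1+ than in flavopiridol and below the random range. After subtracting the median of genes of like GC content and length these were -0.67, -0.58, -0.404, -0.424 and -0.249. The subtraction also takes out the shift shared by all genes, here a median of -0.21. The guanylate-binding protein gene Gbp2 (-2.31), Phlda3 (-2.53), Hspd1 (-1.23) and Bcl2 (-1.11) were among the members that differed. Dendritic cell markers were also lower (-1.11, 4 of 6), led by Flt3 (-2.13). B cell identity genes (0.17) and histones (0.15) were higher in JQ1+ than random lists. Surface receptors had a median of -0.01 that lay above random lists, a mean of -0.34 and 6 of 28 members lower against 1 higher; the median turned to 0.23 after rescaling by the median of ratios. The other lists did not stand apart: class switch (-0.25), plasma cell (-0.09), folding (-0.07), naive B cell (-0.09), germinal centre (-0.07), interleukin-4 (-0.09), NF-kB (-0.20), DNA replication (-0.31), G2/M (-0.09), pause-release factors (-0.09), immediate early (-0.32), oxidative phosphorylation (-0.27), cholesterol (-0.26), ribosomal proteins (-0.15) and integrated stress (-0.37).

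**Figure D2:**
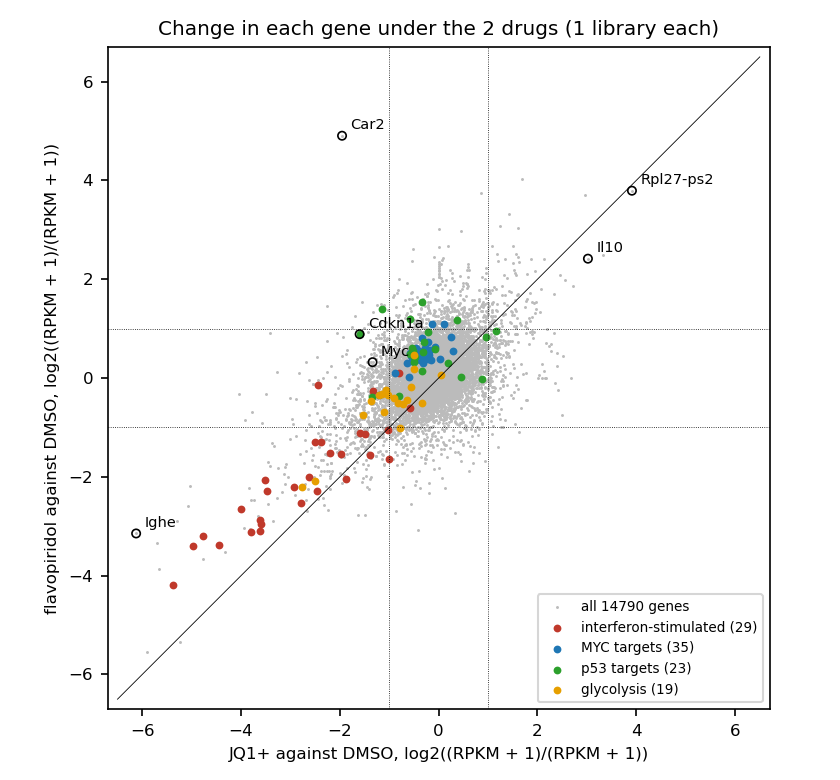
Log2 change of each of 14790 genes with JQ1+ (horizontal) and flavopiridol (vertical) against the same DMSO library, with a pseudocount of 1 RPKM, dotted lines at 2-fold and the diagonal of equal change. Interferon-stimulated genes lie at the lower left, with medians of -2.50 and -2.04, and MYC targets and most p53 targets lie above the diagonal.

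Across genes the changes under the 2 drugs were correlated, with Pearson r = 0.49 and Spearman rho = 0.33 over 14790 genes, which are not independent replicates. Both changes share the DMSO library, and unchanged drug libraries simulated against it gave r = 0.46. The covariance was 0.154, against 0.0402 in the simulation, a difference of 0.114. Genes that rose with both drugs numbered 110, where the same simulation gave 60.6, and 243 fell with both, where it gave 51.5. There were 3 genes that rose with JQ1+ and fell with flavopiridol and 17 that did the reverse. The single DMSO library cannot be divided, so part of this overlap may come from that library.

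**Figure D3:**
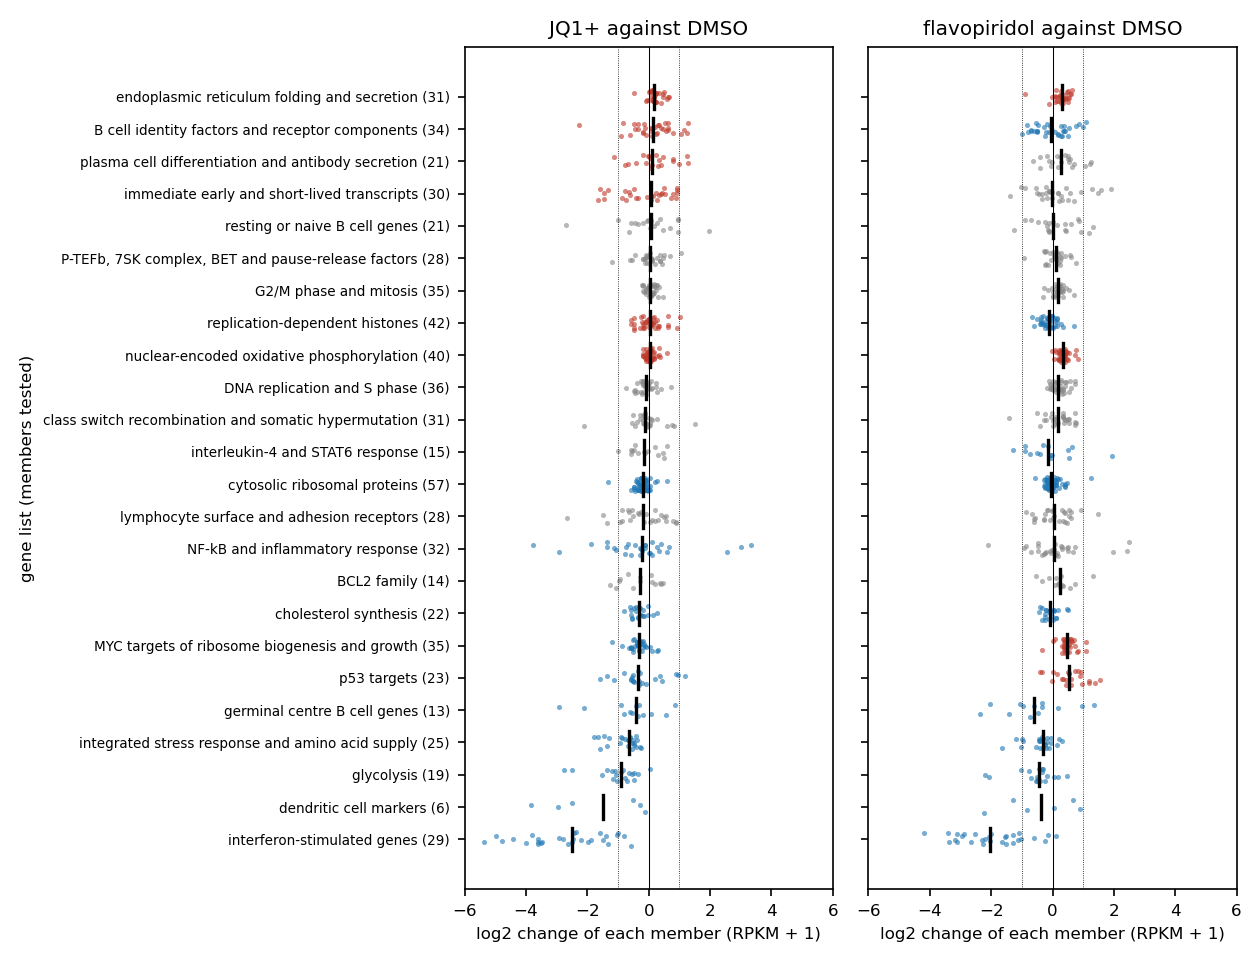
Log2 change against DMSO of each member (points) of 24 gene lists with at least 6 measured members, with JQ1+ on the left and flavopiridol on the right, black bars at list medians and dotted lines at 2-fold. Blue lists lay below and red lists above the range of random lists, and grey lists did not stand apart; the interferon list had medians of -2.50 and -2.04.

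Markers of other cells were few. T cell markers had 4 measured members with medians of -0.22 under JQ1+ and -0.46 under flavopiridol, led by Thy1, which stood at 268, 161 and 196 RPKM in DMSO, JQ1+ and flavopiridol. The 4 myeloid markers had medians of -0.67 and -0.36. Erythroid markers were represented by Car2 and Alas2, stromal and endothelial markers by Pecam1, which fell from 21.7 to 5.18 RPKM with JQ1+, and Acta2, and cytotoxic cells by Prf1 alone at 2.80, 1.99 and 1.30 RPKM. Cd3e was 0.066 RPKM in DMSO. The myeloid marker Lyz2 was at 0.181 RPKM in DMSO, 1.94 in JQ1+ and 0.044 in flavopiridol. It was thus 10.7-fold higher in JQ1+ than in DMSO (interval 2.25 to 84.7), from 48 undivided counts against 5.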

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

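Of the tests in this part, the one of library scaling was chosen after the result was seen. In 4 lists the 2 drugs lay on opposite sides of random lists against the same DMSO library; this reading of a difference between groups was also chosen after the data were seen, and with 1 library per drug none of these differences was tested. MYC targets had medians of -0.33 with JQ1+ and 0.45 with flavopiridol, a JQ1+ to flavopiridol median of -0.85. The p53 targets had -0.35 and 0.55, with -0.91 between the drugs. B cell identity genes had 0.15 and -0.05, with 0.17 between the drugs. With each drug against DMSO, the interval of their median over members included the random median. Replication-dependent histones had 0.03 and -0.11, with 0.15 between the drugs, and near-identical histone copies share reads. The histone interval over members with JQ1+ included the random median, and the histone call with flavopiridol was lost with a minimum of 5 RPKM.

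The MYC and p53 lists were weighed further. After subtracting the median difference of genes of like GC content and length, the medians between the drugs were -0.58 for MYC targets and -0.67 for p53 targets, which argues against GC content or length as the whole cause. The subtraction also takes out the shift shared by all genes (median -0.21), so the smaller values do not measure a GC or length effect. Across genes, the difference between the drugs correlated little with GC content (rho = 0.02) or length (rho = 0.05). After each library was rescaled by the median of ratios they were -0.62 and -0.69, which argues against library scaling as the whole cause. The biological hypothesis, that the drugs had different effects on these programmes, goes with the fall of Myc itself with JQ1+ (194 to 76.2 RPKM) and its level of 243 RPKM with flavopiridol. It stays open, because a difference between single cultures unrelated to the drugs, or between a BET inhibitor and a kinase inhibitor at unequal strength, may give the same values.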

How the results depend on the processing

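No paired analysis was possible because each group had 1 library, and for the same reason no library could be left out. Counts of called genes followed the settings. They are given as higher and lower, in the order JQ1+ against DMSO, flavopiridol against DMSO and JQ1+ against flavopiridol. The main counts were 293 and 782, 525 and 426, and 304 and 1016. With a minimum of 5 RPKM, which tests fewer genes, they were 138 and 471, 229 and 256, and 172 and 566. With a 1.5-fold rule they were 902 and 1877, 1816 and 1118, and 815 and 3097; with a 3-fold rule 75 and 304, 137 and 140, and 95 and 261. A pseudocount of 5, which shrinks the changes of low genes, gave 84 and 363, 139 and 183, and 110 and 329. A pseudocount of 0.1 raised the higher counts to 503 for JQ1+ and 867 for flavopiridol. Rescaling by the median of ratios gave 471 and 633 between the drugs, and its shift of the all-gene median was 0.08, -0.13 and 0.21. The more frequent direction changed for flavopiridol alone, where falls outnumbered rises with a minimum of 5 RPKM, a pseudocount of 5, the 3-fold rule, protein-coding genes or the median of ratios. Alternatives chosen after seeing the data were these: protein-coding genes alone gave 116 higher for JQ1+, 262 and 271 for flavopiridol, and 84 higher between the drugs, and requiring a counting interval that excludes 1 gave 183 higher for JQ1+ and 186 higher between the drugs. The correlation of the drugs was 0.459 with no minimum and 0.543 in protein-coding genes, against 0.491, and in both cases the cause was not tested.

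Of 645 list medians under the alternatives, 611 stayed within the interval of the main median, 31 moved and 3 reversed. The surface receptor median between the drugs turned from -0.01 to 0.23 with the median of ratios and to 0.10 with scaling by the count sum, since both raise all values between the drugs. The dendritic marker median with flavopiridol turned from -0.39 to 0.012 with no minimum, which adds members near 0 RPKM. Interferon, glycolysis, MYC and p53 lists kept their calls in all 3 comparisons under all 9 alternatives. The G2/M list with JQ1+, at percentile 97.485, kept its call in 1 of the 9, the oxidative phosphorylation list with JQ1+ in 5, the pause-release list with JQ1+ in 6, and the naive B cell and BCL2 lists with JQ1+, the plasma cell list with flavopiridol and surface receptors between the drugs in 7. Calls kept in 8 of the 9 were those of NF-kB and surface receptors with JQ1+, of interleukin-4, histones, immediate early genes and dendritic markers with flavopiridol, and of plasma cell and integrated stress genes between the drugs; all other calls were kept in all 9. Of 1743 named gene values, 1624 moved by less than 0.5 log2, 119 by more and none reversed. Depth limits low genes most: counting noise alone gave 135 rises and 148 falls with JQ1+ at the main minimum and 29.6 and 33.8 at 5 RPKM.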

Other observations

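Of the tests in this part, those of other cells (dendritic cells included), of the DMSO library, of interferon-gamma genes, of the pseudogene and of HIF targets were chosen after the results were seen; the interferon-gamma and HIF lists were written when some of their members had been seen in other lists. Genes of antibody variable regions, chosen after their values were seen, lay apart between the drugs. Over 52 kappa variable genes the median log2 change was 0.54 with JQ1+, with 6 at least 2-fold higher and 0 lower, and -0.84 with flavopiridol, with 17 lower and 0 higher. Over 22 heavy variable genes it was 0.76 and -0.63. Genes whose deposited type is antibody constant region took 2.30% of counts in DMSO (Wilson 95% interval 2.29 to 2.30). They took 3.89% in JQ1+ (3.88 to 3.90) and 1.52% in flavopiridol (1.52 to 1.53). Ighe and Ighg2c are typed as protein-coding and are not in these shares.

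Some single transcripts outside the naming rule, chosen after their values were seen, also differed. The nuclear noncoding RNA Malat1 stood at 1666 RPKM in DMSO, 2835 in JQ1+ and 839 in flavopiridol. Rn7sk, the RNA that holds Cdk9 inactive, was at 126091, 129700 and 92049 RPKM. An unnamed small RNA, Gm26461, was at 873 RPKM in DMSO, 22.3 in JQ1+ and 20.4 in flavopiridol. The interferon gene Ifnb1 was at 0.062, 0 and 0.151 RPKM, while the receptor genes Ifnar1 (41.5, 56.6 and 45.5) and Ifnar2 (44.2, 48.4 and 41.8) were within 2-fold. Xist was at 162, 169 and 160 RPKM, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had no counts in any library.

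Interferon-stimulated genes were lower in both drug libraries, with medians of -2.50 and -2.04. The correction for GC content and length left medians of -2.39 and -2.24, which argues against that bias. Abundant transcripts of other cells (Cd3e, Cd3d, Lyz2, S100a8, S100a9, C1qa, C1qb, Siglech, Ncr1 and Nkg7) summed to 0.941 RPKM in DMSO. The interferon list lost 1350 RPKM with flavopiridol and 1901 with JQ1+. This argues against T cells, myeloid cells, plasmacytoid dendritic cells and natural killer cells that carry these transcripts as the source. The sum left out measured members of the fixed marker lists. Among them Thy1, Fcgr4 and Prf1 were each above that sum in DMSO, Thy1 by far the most. The argument therefore does not cover cells marked by those genes alone. Conventional dendritic cells stay open: the measured markers Zbtb46, Flt3, Xcr1 and Batf3 had medians of -1.73 with JQ1+ and -0.39 with flavopiridol, where Batf3 fell (55.9 to 11.1 RPKM) while Zbtb46 (6.63 to 6.85) and Xcr1 (0.918 to 2.59) did not, so a loss of these cells cannot be told apart from changes within B cells. The list also differed between the drugs, by -0.68, less than either fall, so an unusual interferon response in the DMSO culture alone cannot be told apart from loss under both drugs without a further DMSO library. A hypothesis that flavopiridol spared genes induced mainly by interferon-gamma was not borne out: the median of 18 such genes was -0.46 with flavopiridol and -0.89 with JQ1+, both at percentile 0.

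The ribosomal protein pseudogene Rpl27-ps2 lay far apart between DMSO and both drugs, at 6.28, 109 and 99.8 RPKM. The parent gene Rpl27 changed by at most 0.42, which argues against reads that follow the parent's level. The drug libraries differed in Rpl27-ps2 by 0.12. A sequence variant carried by the mice of the DMSO culture alone may give this pattern. The sex-linked genes were alike in all libraries, but they can separate only mice of different sex. The variant therefore cannot be told apart from an effect shared by the drugs. If the DMSO culture came from other mice, the genes lower in both drug libraries would carry that difference too.

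A further hypothesis was that glycolysis genes, at -0.90 and -0.45, may have fallen with other targets of the hypoxia factor HIF. A list of 16 measured HIF targets without glycolytic enzymes had medians of -0.27 with JQ1+, at percentile 3.31, and 0.05 with flavopiridol, at percentile 25.5, so it did not stand apart with either drug. By the criterion as first written, this counted against the hypothesis. The criterion was changed after the result was seen, to ask also that the interval exclude the glycolysis median, because the JQ1+ interval, -0.996 to 0.37, includes -0.90. Under the changed criterion the hypothesis stays open, and Bnip3 (-1.53) and Vegfa (-1.44) were lower with JQ1+ while Bhlhe40 was higher (28.2 to 57.5 RPKM).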
